A study of Mus musculus with 14 samples.

How the data were processed

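RNA from 7 groups of cultured mouse cells was measured on 14 Affymetrix arrays, 2 per group, which the labels call biological repeats. TKO cells lack the 3 DNA methyltransferases Dnmt1, Dnmt3a and Dnmt3b, WT cells carry them, and ntTS cells are trophoblast stem (TS) cells derived after nuclear transfer. The groups were TKO embryonic stem (ES) cells, WT ES cells, WT ES cells in which GATA4 was activated (WT ES+GATA4), WT ntTS cells, TKO ntTS cells, WT TS cells and WT extraembryonic endoderm (XEN) cells. Per the labels, the WT TS and WT XEN groups held 2 lines each, and the other groups 1. Line and genotype could therefore not be separated. The p-values therefore measured only the spread between repeats, which may be technical where both repeats came from 1 line. All 14 columns were assigned to a sample and 0 were left over.

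The deposited values were intensity values, 1 MAS5 signal per probe set on a linear scale, made by the authors with MAS5, per the submitters' processing notes. The MAS5 version, the scaling target and the detection calls were not given in the sources used here. The 2% trimmed means ranged from 213 to 327 and the medians from 32.6 to 58.8 between arrays, so the deposited arrays did not share 1 scaling target over all probe sets. The labelling was a 1-cycle in vitro transcription with biotin, per the labels.

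Of 45101 probe sets, 64 were control probe sets, 34958 carried 1 gene symbol, 932 carried several and 9211 were not listed in the platform annotation. Symbols were updated by Entrez identifier for 34754 probe sets, and 0 symbols changed. No gene was named from a probe set with several symbols, which left out H19. A gene's value was that of its probe set with the highest mean log2 signal, which gave 18194 genes. Genes whose highest group mean lay above 43.6, the median of all deposited signals, were tested. These were 13146 genes, and 5048 lay below. Signals were analysed as log2(signal + 7.65), the added value being the 20th percentile of all deposited signals, so that differences between dim genes were pulled towards 0.

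Differences were fitted with limma 3.58.1 (lmFit and eBayes with trend) in R 4.3.3, with version 1.17.8 of data.table. All 14 arrays entered 1 fit of 7 group means with 7 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the 13146 genes within each of 11 comparisons, and a gene was called at an adjusted p under 0.05. Limma's camera test with a preset correlation of 0.01 was run on gene lists with at least 5 measured members, adjusted over the lists within a comparison. The 20 lists were Pluripotency, Trophoblast stem, Differentiated trophoblast, Primitive endoderm regulators and receptors, Parietal endoderm, Visceral endoderm, Germline genes, X-linked reproductive clusters, Two-cell-stage genes, Imprinted maternally expressed, Imprinted paternally expressed, Methylation machinery, Xist and Y-linked, p53 targets, Interferon response, Immediate early and heat shock, Feeder fibroblast, Epithelial junctions and keratins, Early germ layers, and Proliferation. Of these, 18 were tested, as Two-cell-stage genes had 2 measured members and Xist and Y-linked had 3. Only 9 of the 36 fixed members of X-linked reproductive clusters and 23 of the 35 of Differentiated trophoblast were measured. The lists share some members, such as Eomes, Phlda2, Grb10 and Rhox9.

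Lineage gene sets were made from genes at least 4-fold higher, and called, in 1 of WT ES, WT TS and WT XEN against each of the others. Whole profiles were compared by Pearson correlation across genes, which are not independent replicates. The overlap of the genotype responses was tested with a one-sided Fisher's exact test per direction. Comparisons of ntTS with TS cells, of ntTS or WT ES+GATA4 cells with ES cells, and of XEN with WT ES+GATA4 cells crossed a difference in bacterial spike-in signal that followed the groups.

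The genes named in the text followed a rule. It took the 3 deleted genes with each of their probe sets, and Pou5f1, Nanog, Sox2, Esrrb, Cdx2, Eomes, Elf5, Tfap2c, Fgfr2, Gata4, Gata6, Sox17, Sox7, Pdgfra, Xist and Igf2. It added in each comparison up to 5 genes with the largest rise and 5 with the largest fall among called genes whose groups did not overlap, leaving out clone-type symbols. It took from each list up to 4 called members with the largest difference in the TKO against WT comparisons and up to 3 elsewhere, and up to 2 members where none was called. The lists, the rule, the tests of the comparisons and the alternatives were fixed before the data were examined. The fits restricted to arrays with alike spike-in signals and the tests of explanations for 3 patterns were added later.

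The gene test was run on 13146 genes simulated for TKO ntTS against WT ntTS. It called 64 of 100 genes changed 2-fold, 93 of 100 changed 4-fold and 7 of 12946 unchanged genes (4.27% of its calls). For TKO ES against WT ES, 13146 independent genes were simulated. Camera called 20 of 20 lists of 20 genes shifted 2-fold and 0 of 20 unshifted, with correlated lists not tested.

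A gene with several probe sets can hold probe sets that move apart. Among genes called with several probe sets, 38 of 2174 had a probe set called the other way in TKO ntTS against WT ntTS, and 0 of 486 did in TKO ES against WT ES. The highest share was 242 of 4003, in WT TS against WT ES.

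The alternatives were added values of 1.91 and 30.6, no filter and a filter at 87.3, the mean of a gene's probe sets and every probe set tested on its own. Quantile normalization, equal array medians, eBayes without trend, only the compared groups in the fit, the repeat number as a block and an added 2-fold threshold were also tried. Lists were also tested with an estimated correlation and with fry, which asks whether members move one way on balance and does not compare them with other genes. Lineage sets were also made at 2-fold and 8-fold. Each array was left out in turn.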

Results

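Transcript levels were measured in 7 groups of mouse cell lines with 2 arrays each, so that the number of arrays limited the precision of every comparison. ES cells stood for the epiblast, TS cells for the trophectoderm, XEN cells for the primitive endoderm, and ES cells with activated GATA4 for the parietal endoderm. The array medians lay between 32.6 and 58.8 signal units, and between 10360 and 11816 of 18194 genes lay above 43.6 on each array. The 3'/5' signal ratio was 0.746 to 0.871 for Gapdh and 1.28 to 1.44 for Actb. Signals are given as means ± SD of 2 arrays, and differences as log2 values ± SE with limma's adjusted p-values. Medians of gene lists are given relative to the median of all genes in the comparison, because that median lay above 0 by 0.12 to 0.47 in 9 of the comparisons.

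Bacterial control transcripts split the arrays. The 6 arrays of WT ES+GATA4, WT ntTS and TKO ntTS cells held dap signals of 986 to 1748, and the other 8 arrays held 72.9 to 117. The comparisons of TKO ntTS with WT ntTS, of TKO ES with WT ES, of WT TS with WT ES and of WT XEN with WT ES stayed on 1 side of that split. The difference between the genotype effects was made of 2 comparisons that each stayed on 1 side. In the other 6, the spike-in difference and the group could not be told apart. The WT TS lines had Xist at 7862 (repeat 1) and 82.8 (repeat 2).

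Markers of the reference lineages followed the groups. Pou5f1, a pluripotency regulator, had a signal of 4237 ± 237 in WT ES cells and 4159 ± 294 in TKO ES cells, against 5.19 ± 3.09 in TKO ntTS and 3.37 ± 1.67 in WT TS cells. Elf5, a trophoblast stem cell regulator, had a signal of 3479 ± 267 in TKO ntTS, 4078 ± 1.56 in WT ntTS and 3155 ± 93.2 in WT TS cells, against 1.73 ± 0.0749 in WT ES cells. Gata6, a primitive endoderm regulator, had a signal of 4659 ± 463 in WT XEN and 3957 ± 1014 in WT ES+GATA4 cells, against 18.7 ± 2.9 in WT ES cells.

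**Figure D1:**
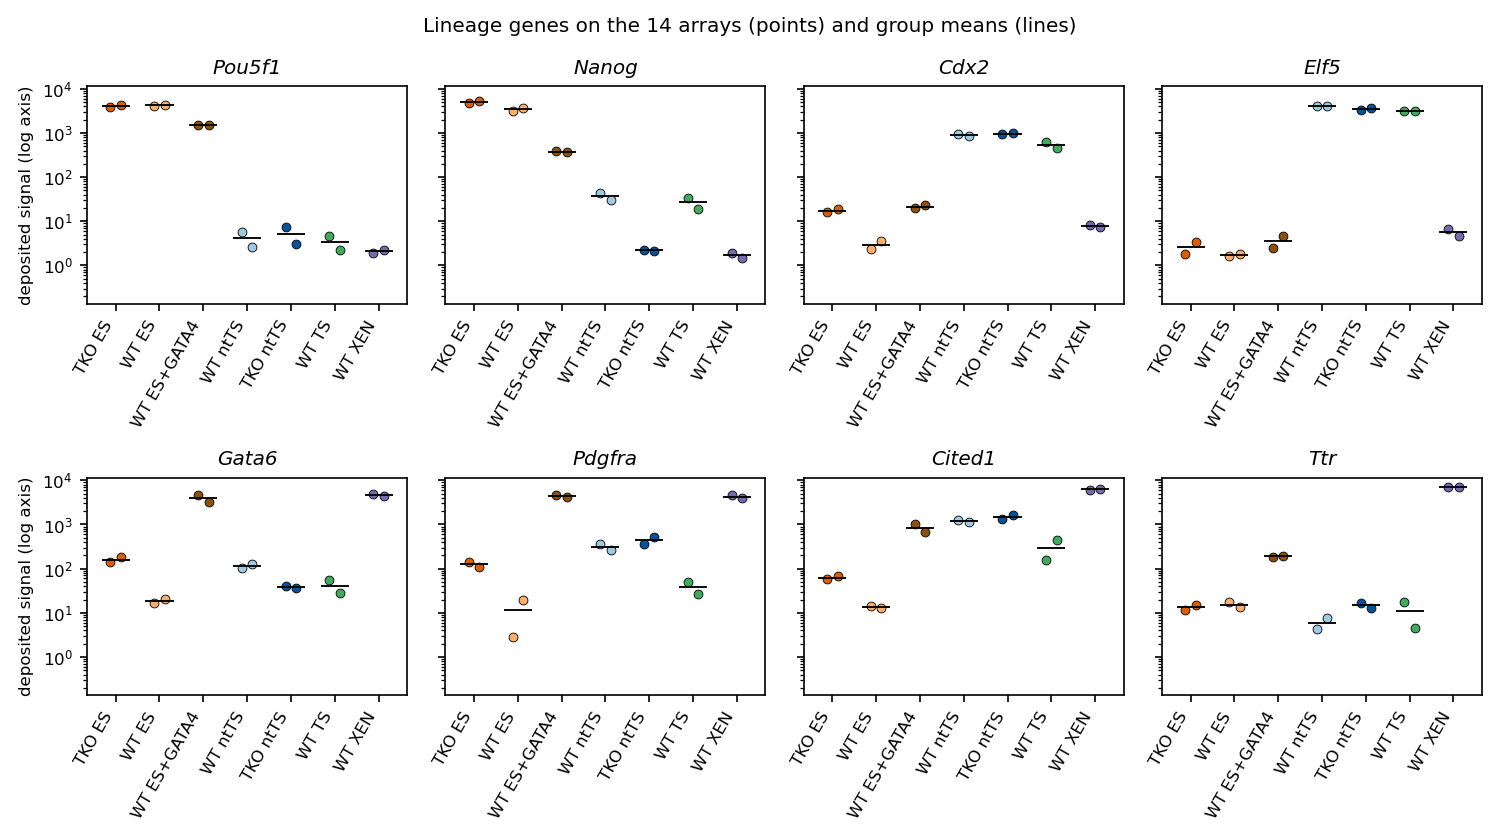
Signal (log axis, deposited MAS5 units) of 8 lineage genes on each of the 14 arrays, 1 point per array, grouped by cell type. Pou5f1 and Nanog are bright in the ES groups, Cdx2 and Elf5 in the ntTS and TS groups, and Gata6 and Pdgfra in the XEN and GATA4 groups, Gata6 in WT XEN cells at 4659 ± 463.

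The deleted genes were read on every probe set. All 3 Dnmt1, 5 Dnmt3a and 2 Dnmt3b probe sets were lower on both TKO arrays than on both WT arrays, in ES and in ntTS cells. Dnmt1 had a signal of 123 ± 19.8 in TKO ES against 2143 ± 17.4 in WT ES cells, and 308 ± 48.2 in TKO ntTS against 1747 ± 3.51 in WT ntTS cells. Dnmt3a fell with a log2 difference of -7.37 ± 0.23 in ES and -3.28 ± 0.23 in ntTS cells, and Dnmt3b with -3.60 ± 0.18 and -4.07 ± 0.18. Where the probes lie relative to the deleted parts was not given in the sources used here.

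The comparison of TKO ntTS with WT ntTS cells asked what the loss of the DNA methyltransferases changes in cells of the trophoblast lineage. The trophoblast stem cell regulators Cdx2 and Elf5 were not called, and placental hormone and protease transcripts were abundant in TKO ntTS cells. Germline genes were higher, as were the X-linked homeobox gene Rhox13 and the imprinted noncoding RNAs Meg3, Rian and Mirg. The growth factor gene Igf2, the imprinted growth restrictor Phlda2 and 12 of 22 fibroblast markers were lower. The test called 3065 genes higher and 1132 lower, of which 1667 differed at least 2-fold. The median of all genes lay at 0.18, and the split was 2340 higher and 2678 lower after quantile normalization and 1578 and 2376 after equal medians. The count of 4197 fell without some of the compared arrays. The 719 genes on the Klf2 chromosome had a relative median of 0.204, above all 1000 random gene draws. A chromosome of 1027 genes lay below them (-0.079) and the rest within.

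Placental hormone and protease genes rose in TKO ntTS cells. Prl4a1, of the placental prolactin family, rose from 8.89 ± 9.14 to 13739.9 ± 1270.4 (9.81 ± 0.38, adjusted p = 2.44e-12). Prl8a9 (6.78 ± 0.42), Prl7d1 (6.66 ± 0.36) and Ctsq, a placental cathepsin (6.67 ± 0.39), rose too. In the Differentiated trophoblast list 18 of 23 rose and 2 fell (18 and 3 adjusted over the list alone), with a median of 4.34 relative to all genes (adjusted p = 1.17e-10). Among the genes with the largest rises were also Rhox13, Ceacam15, of the carcinoembryonic antigen family (7.74 ± 0.32, adjusted p = 6.56e-12), and Srgn, the core protein of a granule proteoglycan (7.68 ± 0.19, adjusted p = 3.11e-15).

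Trophoblast stem cell regulators moved apart. Cdx2 (0.076 ± 0.23, adjusted p = 0.831) and Elf5 (-0.23 ± 0.20, adjusted p = 0.399) did not pass, while Eomes (0.93 ± 0.21, adjusted p = 0.00244), Tfap2c (0.99 ± 0.16) and Ets2 (1.40 ± 0.23) rose and Esx1 fell (-2.21 ± 0.29). In the Trophoblast stem list 6 of 22 rose and 2 fell (6 and 2 adjusted over the list alone). After quantile normalization 5 rose and 5 fell, and splits of other lists moved towards falls too. The Trophoblast stem list was not called (adjusted p = 0.701). Pluripotency genes also went both ways: Tbx3 (-2.78 ± 0.23) and Nanog (-2.16 ± 0.23) fell, while Dppa5a (1.81 ± 0.16) rose. Nanog was dim in both groups, at 2.19 ± 0.124 and 36.9 ± 10.1. In the Pluripotency list 6 of 25 rose and 6 fell (6 and 7 adjusted over the list alone) (adjusted p = 0.193).

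Most genes of the Germline list rose. Dazl, an RNA-binding protein of germ cells, went from 24 ± 17.4 to 644 ± 106 (4.47 ± 0.37, adjusted p = 4.56e-08). Gpat2 (5.45 ± 0.30), the testis ADP/ATP carrier Slc25a31 (4.07 ± 0.28) and Gtsf1 (3.96 ± 0.29) rose as well. Of Germline genes, 27 of 38 rose and 1 fell (30 and 1 adjusted over the list alone), with a median of 1.47 relative to all genes (adjusted p = 8.53e-10). Among X-linked reproductive genes, the homeobox gene Rhox13 rose to 2318 ± 221 from 2.95 ± 2.14 (7.79 ± 0.26, adjusted p = 1.68e-13), followed by Rhox9 (5.03 ± 0.30) and Magea5 (3.82 ± 0.30). In that list 5 of 9 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 2.23 relative to all genes (adjusted p = 0.00693, and adjusted p = 0.087 with an estimated correlation). Of Two-cell-stage genes, 2 were measured and Usp17la rose (1.34 ± 0.40, adjusted p = 0.0157). It was not called after quantile normalization or equal medians, nor without WT ntTS repeat 1 (0.65), TKO ntTS repeat 1 (1.22) or TKO ntTS repeat 2 (1.46).

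Imprinted genes went in both directions. Igf2 fell from 16115 ± 788 to 179.9 ± 12.4 (-6.43 ± 0.28, adjusted p = 1.11e-11), and Phlda2 fell from 1719.8 ± 10.3 to 32.4 ± 16.6 (-5.50 ± 0.30, adjusted p = 2.30e-10). The maternally expressed noncoding RNAs Mirg (5.29 ± 0.24), Rian (4.63 ± 0.26) and Meg3 (3.69 ± 0.18) rose, as did the paternally expressed Zdbf2 (3.08 ± 0.27). In the maternally expressed list 3 of 25 rose and 6 fell (3 and 6 adjusted over the list alone), and in the paternally expressed list 12 of 27 rose and 3 fell (12 and 3 adjusted over the list alone). Neither list was called (adjusted p = 0.211 and adjusted p = 0.209).

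Of 22 markers of fibroblasts, the feeder cells on which both ntTS lines were grown, 12 were called lower in TKO ntTS cells. The cytoskeletal genes Tagln (-2.98 ± 0.20, adjusted p = 3.74e-09) and Acta2 (-2.30 ± 0.19) and the collagen crosslinker Lox (-1.55 ± 0.32) fell. In the Feeder fibroblast list 0 of 22 rose and 12 fell (0 and 12 adjusted over the list alone), with a median of -1.01 relative to all genes (adjusted p = 1.24e-09). Per the labels, the feeders were removed by plating for 30 min. The other largest falls were those of Gna13, a G protein subunit (-5.03 ± 0.16, adjusted p = 1.23e-13), Slc16a6, a transporter (-4.54 ± 0.20), and Amz2, a peptidase (-4.28 ± 0.20), which are neighbours in the GRCm38.p6 assembly.

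Other lists held changes in single genes and were not called in the main setting. With every probe set tested on its own, Pluripotency (adjusted p = 0.0059), Parietal endoderm (0.046) and Methylation machinery (1.21e-04) were called lower, as was Methylation machinery with only the compared groups in the fit (0.012) and p53 targets with the mean of probe sets (0.038). The endoderm genes Gata6 (-1.42 ± 0.24) and Fst (-1.64 ± 0.25) fell, and Amn rose (2.89 ± 0.24). Of Primitive endoderm regulators and receptors 4 of 14 rose and 4 fell (5 and 5 adjusted over the list alone) (adjusted p = 0.465), of Parietal endoderm 4 of 15 rose and 4 fell (4 and 4 adjusted over the list alone) (adjusted p = 0.303), and of Visceral endoderm 2 of 16 rose and 0 fell (2 and 0 adjusted over the list alone) (adjusted p = 0.856). In Methylation machinery 6 of 17 rose and 4 fell (6 and 5 adjusted over the list alone) (adjusted p = 0.193), the 3 deleted genes among the falls and Dnmt3l among the rises (1.87 ± 0.18). Of p53 targets 4 of 21 rose and 7 fell (4 and 8 adjusted over the list alone) (adjusted p = 0.0779), and of Interferon response 3 of 17 rose and 4 fell (3 and 4 adjusted over the list alone) (adjusted p = 0.597). Immediate early and heat shock genes moved apart, with Egr1 down (-2.75 ± 0.24) and Fosl1 up (2.54 ± 0.38), and 9 of 19 rose and 5 fell (10 and 6 adjusted over the list alone) (adjusted p = 0.669). Of Epithelial junctions and keratins 5 of 21 rose and 6 fell (5 and 6 adjusted over the list alone) (adjusted p = 0.193), with Cldn7 lower (-2.66 ± 0.33) and Krt19 higher (2.38 ± 0.22). In Early germ layers 3 of 13 rose and 1 fell (3 and 1 adjusted over the list alone) (adjusted p = 0.777). Of Proliferation 3 of 24 rose and 5 fell (3 and 6 adjusted over the list alone) (adjusted p = 0.0779), and this list was called lower after quantile normalization (adjusted p = 0.020) and equal medians (adjusted p = 0.024). Xist and Y-linked genes had 3 measured members and none was called, Xist at 1.45 ± 1.08, adjusted p = 0.328. Xist was called, at the same difference of 1.45, without WT TS repeat 1 or WT TS repeat 2. The mean of the Trophoblast stem, Primitive endoderm, maternally expressed and Early germ layers lists, not taken relative to all genes, was above 0. It lay below the median of all genes (0.18), and the relative medians and tests of these lists pointed lower. The relative median and the test differed in direction for Visceral endoderm (-0.067, test higher) and Interferon response (0.17, test lower).

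**Figure D2:**
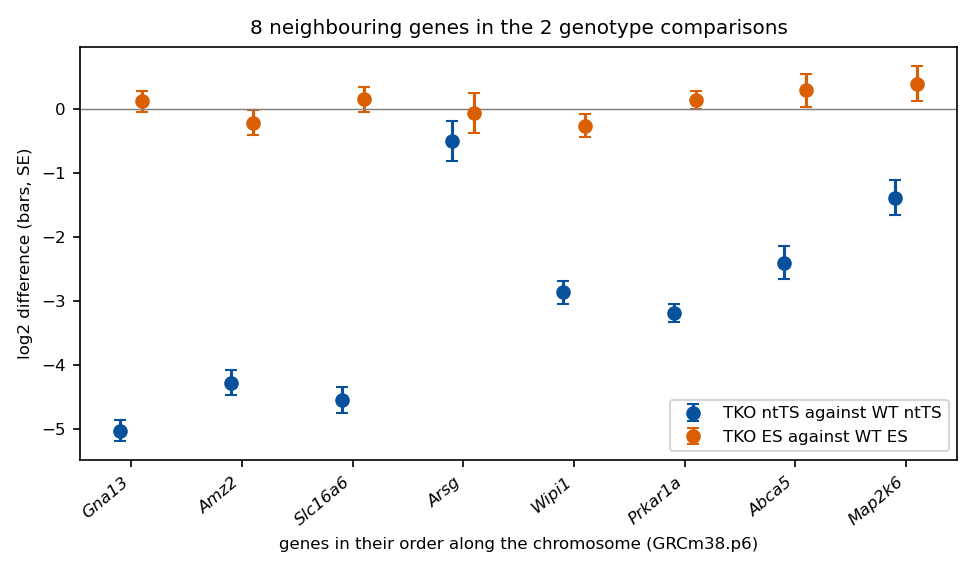
Log2 difference with SE bars (y axis) of 8 neighbouring genes in the gene order of GRCm38.p6 (x axis), 1 point per gene for TKO ntTS against WT ntTS and 1 for TKO ES against WT ES. Gna13, Amz2 and Slc16a6 lie lowest in ntTS cells, at -5.03 ± 0.16, -4.28 ± 0.20 and -4.54 ± 0.20, and the ES points lie between -0.25 and 0.40.

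**Figure D3:**
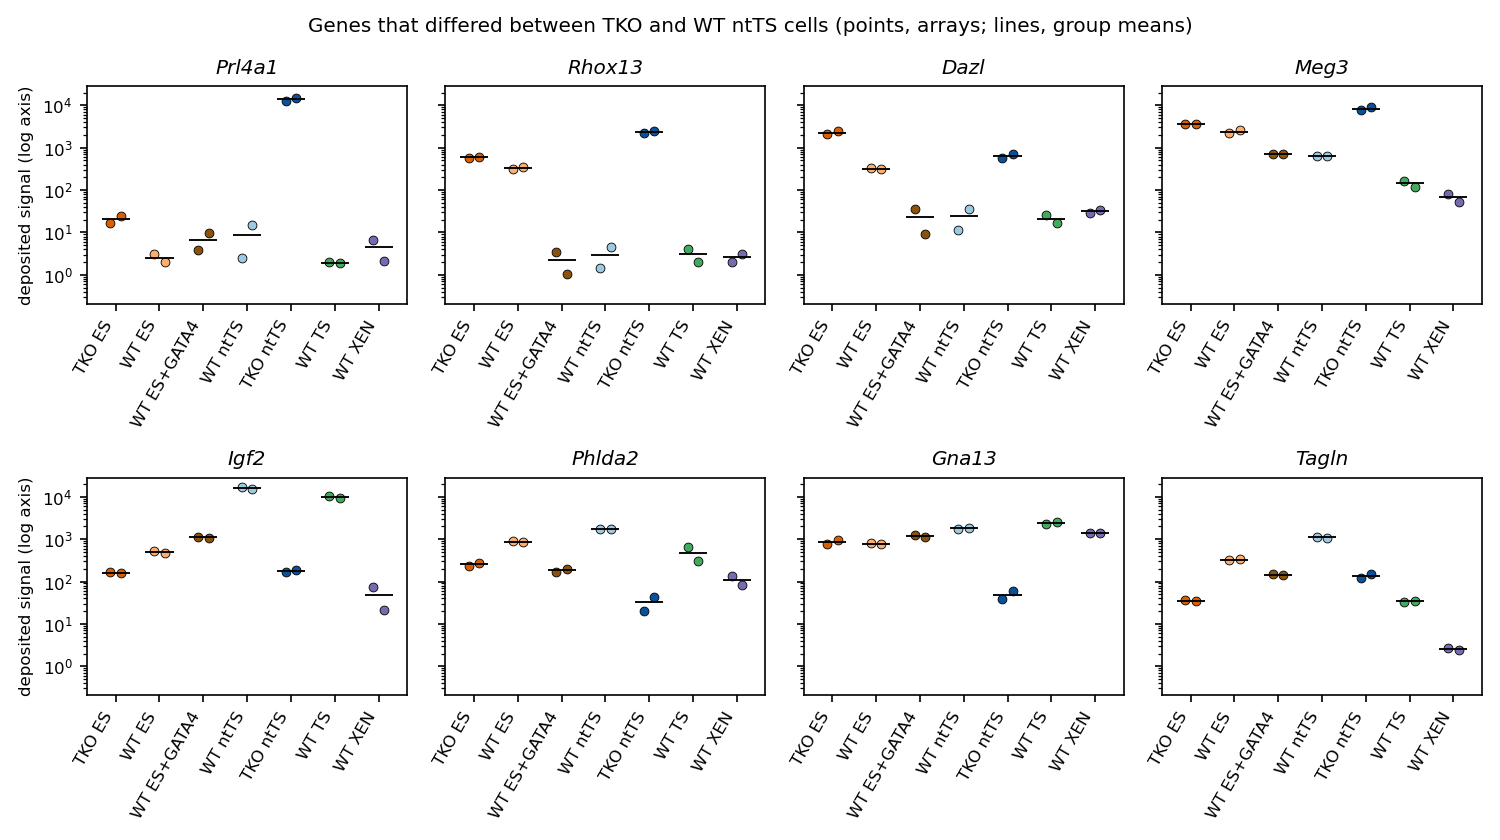
Signal (log axis, deposited MAS5 units) of 8 genes on each of the 14 arrays, 1 point per array. Prl4a1, Rhox13, Dazl and Meg3 lie higher in TKO ntTS than in WT ntTS cells and Igf2, Phlda2, Gna13 and Tagln lower, Prl4a1 at 13739.9 ± 1270.4 against 8.89 ± 9.14.

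TKO ES cells were compared with WT ES cells to see the same loss in cells of the epiblast lineage. The core pluripotency regulators Pou5f1 and Nanog were not called. The Primitive and Parietal endoderm lists were higher in TKO ES cells, the latter not with an estimated correlation (adjusted p = 0.0515). The Germline and X-linked reproductive lists were higher as well. The fibroblast markers Col1a1, Col3a1 and Tagln were among 6 of 22 called lower, and these cells were grown without feeders, per the labels. The test called 553 genes higher and 432 lower, 438 of them at least 2-fold different. The Klf2 chromosome lay below random gene draws (-0.105), a chromosome of 1081 genes above them (0.096) and the rest within. Whether such shifts belong to the lines or the genotype was not tested. The count of 985 fell when any compared array was left out. It was 1616 after quantile normalization, with 842 higher and 774 lower.

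Most primitive and some parietal endoderm genes rose in TKO ES cells. Visceral endoderm was not called (adjusted p = 0.213), with 5 of 16 higher and 1 lower (5 and 3 adjusted over the list alone). The receptor gene Cubn (3.03 ± 0.22, adjusted p = 6.70e-08), the growth factor receptor gene Pdgfra (2.96 ± 0.32) and the regulators Gata6 (2.66 ± 0.24) and Sox17 (1.57 ± 0.27) rose. Gata6 went from 18.7 ± 2.9 to 160.1 ± 30.5, below its 3957 ± 1014 in WT ES+GATA4 cells. Of Primitive endoderm regulators and receptors, 9 of 14 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 1.55 relative to all genes (adjusted p = 1.11e-12). The basement membrane genes Lama1 (2.54 ± 0.32) and Col4a1 (1.99 ± 0.14) rose, and of Parietal endoderm 6 of 15 rose and 0 fell (9 and 1 adjusted over the list alone), with a median of 0.55 relative to all genes (adjusted p = 1.20e-10, and adjusted p = 0.0515 with an estimated correlation). Pou5f1 (-0.027 ± 0.22, adjusted p = 0.971) and Nanog (0.55 ± 0.23, adjusted p = 0.18) did not pass. In the Pluripotency list 2 of 25 rose and 1 fell (3 and 1 adjusted over the list alone) (adjusted p = 0.713).

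Some germline and X-linked reproductive genes rose in TKO ES cells. The cancer-testis antigen gene Magea5 (4.48 ± 0.30, adjusted p = 2.36e-08) had the largest rise, and Magea6 (3.57 ± 0.51) and the germline gene Dazl (2.79 ± 0.37) rose too. Of Germline genes 12 of 38 rose and 0 fell (16 and 1 adjusted over the list alone), with a median of 0.59 relative to all genes (adjusted p = 7.22e-08). Of X-linked reproductive clusters 4 of 9 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 1.09 relative to all genes (adjusted p = 4.99e-09). Srgn (3.65 ± 0.19) and Trim43a (3.20 ± 0.38) were among the largest rises. Plagl1 (2.64 ± 0.36) and Peg3 (1.37 ± 0.12) rose and Igf2 fell (-1.58 ± 0.28) among paternally expressed genes, where 5 of 27 rose and 2 fell (5 and 2 adjusted over the list alone), with a median of 0.22 relative to all genes (adjusted p = 0.0043, and adjusted p = 0.381 with an estimated correlation).

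Some fibroblast markers fell in TKO ES cells. Col3a1 went from 297 ± 73.9 to 15.8 ± 0.134 (-3.68 ± 0.26, adjusted p = 3.59e-08), with Col1a1 (-3.64 ± 0.33) and Tagln (-2.96 ± 0.20) lower too. In the Feeder fibroblast list 0 of 22 rose and 6 fell (1 and 10 adjusted over the list alone), with a median of -0.48 relative to all genes (adjusted p = 5.74e-08). In Methylation machinery 0 of 17 rose and 4 fell (0 and 4 adjusted over the list alone), the 3 deleted genes among the falls. That list was called lower (adjusted p = 0.00358, and adjusted p = 0.451 with an estimated correlation). Its mean was -0.86 but its relative median 0.011, so the 3 deleted genes may set the whole call, which was not tested. Sox21 (1.64 ± 0.26, adjusted p = 5.37e-04) rose and Bmp4 (-1.33 ± 0.16) fell in the Trophoblast stem list, which was not called (adjusted p = 0.0903) except without TKO ES repeat 1 (adjusted p = 0.043) or WT ES repeat 1 (0.047), with the mean of probe sets (0.017) or with every probe set (0.0028). In the Differentiated trophoblast list 1 of 23 rose and 2 fell (1 and 2 adjusted over the list alone) (adjusted p = 0.713). The lists not called had adjusted p-values from 0.090 to 0.94.

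**Figure D4:**
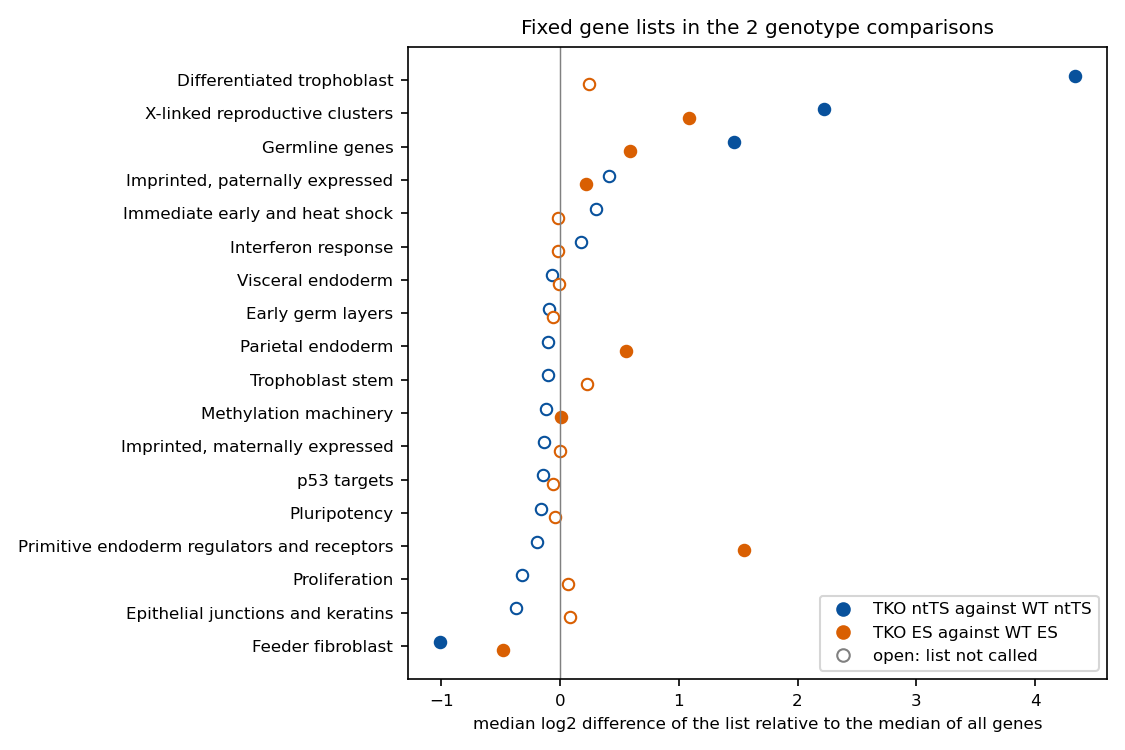
Median log2 difference of the 18 tested gene lists relative to all genes (x axis), TKO ntTS against WT ntTS in blue and TKO ES against WT ES in orange, filled points for lists called by camera and open points for the others. The Differentiated trophoblast list lies at 4.34 in ntTS and 0.24 in ES cells.

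The difference between the genotype effects in ntTS and ES cells was tested as an interaction, to find genes whose change depended on the cell type. Placental genes had higher effects in ntTS cells. The Primitive endoderm list had a lower effect in ntTS cells, a call that was lost with an estimated correlation (adjusted p = 0.119). Igf2 and Gna13 had lower effects in ntTS cells. The interaction called 1763 genes higher and 711 lower, 1586 of them at least 2-fold, around a median of 0.17 over all genes. The split was 1600 and 1713 after quantile normalization and 960 and 1179 after equal medians. The count of 2474 was 1623 without TKO ES repeat 1, 1641 without WT ES repeat 2 and 1613 without TKO ntTS repeat 2.

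Prl4a1 (8.34 ± 0.54, adjusted p = 9.83e-09), the secreted phospholipase gene Pla2g5 (7.52 ± 0.56) and Rhox13 (6.99 ± 0.36) had higher genotype effects in ntTS cells. In Differentiated trophoblast 17 of 23 had a higher and 2 a lower effect in ntTS cells (18 and 2 adjusted over the list alone), with a median of 3.65 relative to all genes (adjusted p = 6.18e-13). Of Germline genes 16 of 38 had a higher and 4 a lower effect in ntTS cells (20 and 4 adjusted over the list alone), with a median of 1.46 relative to all genes (adjusted p = 0.00287, and adjusted p = 0.336 with an estimated correlation). Lower effects were found for Gna13 (-5.16 ± 0.23, adjusted p = 5.59e-11), Igf2 (-4.85 ± 0.40), the pantetheinase gene Vnn1 (-4.88 ± 0.39) and Gata6 (-4.08 ± 0.34). Of Primitive endoderm regulators and receptors 1 of 14 had a higher and 7 a lower effect in ntTS cells (1 and 8 adjusted over the list alone), with a median of -1.45 relative to all genes (adjusted p = 3.25e-07, and adjusted p = 0.119 with an estimated correlation). Of Parietal endoderm 2 of 15 had a higher and 6 a lower effect in ntTS cells (2 and 6 adjusted over the list alone), with a median of -0.55 relative to all genes (adjusted p = 5.58e-06, and adjusted p = 0.308 with an estimated correlation). The Feeder fibroblast effect was not called different (adjusted p = 0.297) except with an added value of 30.6 (adjusted p = 0.034) or every probe set (adjusted p = 0.046), with Col1a1 higher (2.93 ± 0.47) and Col5a2 lower (-1.92 ± 0.41).

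Genes called higher in TKO cells of both types numbered 218, where independent lists would share 129 (one-sided Fisher's exact test, p = 4.12e-18). Genes called lower in both numbered 101, where 37.2 would be shared (one-sided Fisher's exact test, p = 2.80e-21). After quantile normalization 285 were higher and 277 lower in both, where 149.9 and 158 would be shared. After equal medians they were 125 and 144, where 52.6 and 73.9 would be. With only the compared groups they were 387 and 197, where 286 and 99.1 would be. Another 86 and 58 genes were called in opposite directions, with no expected numbers computed. The log2 differences correlated across genes with r = 0.16 and Spearman's rho = 0.13, and genes are not independent replicates. The 218 and the 101 both fell without some of the compared arrays.

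WT ntTS cells were compared with WT TS cells to see how trophoblast stem cells from nuclear transfer differ from those of fertilised embryos. The trophoblast regulators Elf5 and Eomes were not called. Fibroblast markers were much higher in the ntTS cells, which had spent 1 day on a feeder dish before collection against 3 days for TS cells. The lipid carrier gene Apoe was lower. The test called 2778 genes higher and 1040 lower, 1485 at least 2-fold, around a median of 0.16. The split was 2573 and 1949 after quantile normalization and 2058 and 1237 after equal medians. The count of 3818 was 2173 without WT ntTS repeat 1 and 2338 without WT ntTS repeat 2.

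S100a4, a calcium-binding protein of fibroblasts (6.70 ± 0.33, adjusted p = 3.63e-11), the matrix glycoprotein gene Thbs1 (6.01 ± 0.22), Col1a1 (5.15 ± 0.33) and Tagln (4.71 ± 0.20) rose. In the Feeder fibroblast list 21 of 22 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 3.08 relative to all genes (adjusted p = 1.42e-19). The largest falls were those of Apoe (-4.66 ± 0.49, adjusted p = 1.01e-06) and Rpgrip1 (-4.51 ± 0.19). Elf5 (0.37 ± 0.20, adjusted p = 0.173) and Eomes (0.27 ± 0.21, adjusted p = 0.364) did not pass, and Cdx2 rose (0.78 ± 0.23, adjusted p = 0.014). Cdx2 was not called without WT ntTS repeat 1 (0.72), WT ntTS repeat 2 (0.84) or WT TS repeat 2 (0.55). Of Trophoblast stem 6 of 22 rose and 2 fell (6 and 2 adjusted over the list alone) (adjusted p = 0.628). The pluripotency-associated genes Tbx3 (3.06 ± 0.23) and Klf4 (2.20 ± 0.19) rose, in a list that was not called (adjusted p = 0.0859). The Feeder fibroblast list was the 1 list called, and 4 lists were called without WT TS repeat 1, with Pluripotency (adjusted p = 0.041), X-linked reproductive clusters (adjusted p = 0.042) and Immediate early and heat shock (adjusted p = 0.045) added. Pluripotency was also called without a filter (adjusted p = 0.036) and with every probe set (adjusted p = 0.0055), and Immediate early and heat shock with the mean of probe sets (adjusted p = 0.041). Spike-in signal, feeder cells, days on the dish and cell origin could not be told apart here.

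TKO ntTS cells were compared with WT TS cells, the trophectoderm reference. Placental hormone and protease genes were higher, as were germline genes and fibroblast markers. The noncoding RNA Meg3 was higher and Igf2 was lower. The test called 5049 genes higher and 959 lower, 2466 at least 2-fold, around a median of 0.35. The split was 3058 and 2616 after quantile normalization and 2343 and 2099 after equal medians. The count of 6008 was 3958 without TKO ntTS repeat 2.

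Prl4a1 (10.48 ± 0.38, adjusted p = 4.98e-13), Prl7a1 (8.43 ± 0.34) and the placental cathepsin gene Ctsj (7.98 ± 0.51) had the largest rises with Prl8a9 and Rhox13. In Differentiated trophoblast 17 of 23 rose and 2 fell (17 and 2 adjusted over the list alone), with a median of 3.41 relative to all genes (adjusted p = 3.60e-07). Tex13b (5.57 ± 0.22), Gpat2 (5.35 ± 0.30) and Dazl (4.51 ± 0.37) rose, and of Germline genes 33 of 38 rose and 0 fell (33 and 0 adjusted over the list alone), with a median of 1.93 relative to all genes (adjusted p = 8.68e-09). Meg3 rose (5.81 ± 0.18) and Igf2 fell (-5.72 ± 0.28). Fibroblast markers rose, S100a4 by 5.97 ± 0.33, and in that list 21 of 22 rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 1.41 relative to all genes (adjusted p = 1.77e-07). Of Methylation machinery 5 of 17 rose and 4 fell (5 and 4 adjusted over the list alone), with a median of -0.30 relative to all genes (adjusted p = 0.0143, and adjusted p = 0.776 with an estimated correlation). The 3 deleted genes are among its 4 falls, and the call was not tested without them. Of Proliferation 4 of 24 rose and 7 fell (4 and 7 adjusted over the list alone), with a median of -0.44 relative to all genes (adjusted p = 0.00301, and adjusted p = 0.776 with an estimated correlation). The Proliferation list was not called with every probe set tested on its own. Eomes (1.20 ± 0.21, adjusted p = 1.68e-04) and Hand1 (1.31 ± 0.20) rose, and the Trophoblast stem list was not called (adjusted p = 0.873). The paternally expressed list was not called (adjusted p = 0.129) but was called higher after quantile normalization (adjusted p = 0.028), after equal medians (0.021), with every probe set (0.043), and without TKO ES repeat 2 (0.043) or WT TS repeat 2 (0.033). Spike-in signal, feeder cells and group could not be told apart here.

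TKO ntTS cells were compared with TKO ES cells to see the lineage difference in the absence of the DNA methyltransferases. Pou5f1 and Nanog were near background in TKO ntTS cells, and 20 of 25 Pluripotency genes were lower. Differentiated trophoblast genes were higher. The Trophoblast stem and Epithelial lists were higher and the Germline list lower, and these 3 calls were lost with an estimated correlation (adjusted p = 0.107, 0.391 and 0.107). The test called 6313 genes higher and 1773 lower, 4392 at least 2-fold, around a median of 0.47. The split was 3628 and 4043 after quantile normalization and 2896 and 4226 after equal medians. Culture medium, feeders and spike-in signal changed together with the cell type, and could not be told apart from it.

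Nanog (-9.01 ± 0.23, adjusted p = 7.72e-16), the Nodal co-receptor gene Tdgf1 (-8.94 ± 0.21) and Pou5f1 (-8.36 ± 0.22) fell. In Pluripotency 1 of 25 rose and 20 fell (1 and 20 adjusted over the list alone), with a median of -3.43 relative to all genes (adjusted p = 1.61e-22). Elf5 (8.41 ± 0.20, adjusted p = 3.46e-16), Cdx2 (5.28 ± 0.23) and Eomes (5.18 ± 0.21) rose. Of Trophoblast stem 17 of 22 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 3.21 relative to all genes (adjusted p = 1.78e-07, and adjusted p = 0.107 with an estimated correlation). Of Differentiated trophoblast 21 of 23 rose and 1 fell (21 and 1 adjusted over the list alone), with a median of 4.89 relative to all genes (adjusted p = 1.78e-07). Krt18 rose (6.08 ± 0.13), and of Epithelial junctions and keratins 17 of 21 rose and 3 fell (17 and 3 adjusted over the list alone), with a median of 1.56 relative to all genes (adjusted p = 0.00153, and adjusted p = 0.391 with an estimated correlation). In Feeder fibroblast 20 of 22 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 1.37 relative to all genes (adjusted p = 0.00162, and adjusted p = 0.0671 with an estimated correlation). Usp26 fell (-4.76 ± 0.43), and of Germline genes 7 of 38 rose and 19 fell (8 and 21 adjusted over the list alone), with a median of -1.23 relative to all genes (adjusted p = 2.75e-05, and adjusted p = 0.107 with an estimated correlation). In Methylation machinery 6 of 17 rose and 8 fell (6 and 9 adjusted over the list alone), with a median of -0.82 relative to all genes (adjusted p = 0.00475, and adjusted p = 0.391 with an estimated correlation). Of Immediate early and heat shock 13 of 19 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.60 relative to all genes (adjusted p = 0.0195, and adjusted p = 0.588 with an estimated correlation). Primitive endoderm regulators and receptors were called lower (6 of 14 rose and 7 fell (6 and 7 adjusted over the list alone); adjusted p = 0.011, and adjusted p = 0.362 with an estimated correlation), but not after quantile normalization (adjusted p = 0.077) or equal medians (adjusted p = 0.12). Early germ layers were called lower (5 of 13 rose and 7 fell (5 and 7 adjusted over the list alone); adjusted p = 0.00162, and adjusted p = 0.281 with an estimated correlation), but not after those rescalings (adjusted p = 0.064 and 0.061). Proliferation was called lower after both (0.0091 and 0.0032), with every probe set (0.0027) and without TKO ES repeat 1 (0.048), TKO ntTS repeat 2 (0.045) or either WT ES+GATA4 repeat (0.041 and 0.042). Interferon response was called higher after equal medians (0.020) and with only the compared groups (0.033).

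WT ntTS cells were compared with WT ES cells for the same lineage difference with the methyltransferases present. Pluripotency and germline genes were lower, and Igf2 was higher. The Trophoblast stem, Epithelial and Parietal endoderm lists were higher, and these 3 calls were lost with an estimated correlation (adjusted p = 0.0615, 0.206 and 0.281). The test called 5225 genes higher and 2457 lower, 4078 at least 2-fold, around a median of 0.30. The split was 3933 and 3921 after quantile normalization and 3242 and 3791 after equal medians. Medium, feeders and spike-in signal again changed with the cell type, and could not be told apart from it.

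Elf5 (8.77 ± 0.20, adjusted p = 1.91e-16), the matrix protein gene Tinagl1 (7.33 ± 0.19), Cdx2 (6.44 ± 0.23) and Igf2 (5.01 ± 0.28) rose. Of Trophoblast stem 20 of 22 rose and 0 fell (21 and 1 adjusted over the list alone), with a median of 2.61 relative to all genes (adjusted p = 2.42e-10, and adjusted p = 0.0615 with an estimated correlation). Tdgf1 (-9.12 ± 0.21, adjusted p = 2.49e-16) and Pou5f1 (-8.50 ± 0.22) fell, and of Pluripotency 0 of 25 rose and 20 fell (0 and 20 adjusted over the list alone), with a median of -2.65 relative to all genes (adjusted p = 3.55e-16). In Parietal endoderm 11 of 15 rose and 1 fell (11 and 2 adjusted over the list alone), with a median of 1.78 relative to all genes (adjusted p = 3.76e-04, and adjusted p = 0.281 with an estimated correlation). Hormad1, a meiotic gene, fell (-5.91 ± 0.34), and of Germline genes 4 of 38 rose and 24 fell (4 and 24 adjusted over the list alone), with a median of -2.06 relative to all genes (adjusted p = 2.72e-09). In Epithelial junctions and keratins 18 of 21 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 1.92 relative to all genes (adjusted p = 1.27e-06, and adjusted p = 0.206 with an estimated correlation). In Feeder fibroblast 19 of 22 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 1.33 relative to all genes (adjusted p = 5.49e-05). Of Methylation machinery 4 of 17 rose and 9 fell (4 and 9 adjusted over the list alone), with a median of -0.79 relative to all genes (adjusted p = 0.0012, and adjusted p = 0.332 with an estimated correlation). Of Immediate early and heat shock 15 of 19 rose and 3 fell (16 and 3 adjusted over the list alone), with a median of 1.18 relative to all genes (adjusted p = 0.0087, and adjusted p = 0.487 with an estimated correlation). Differentiated trophoblast was not called (12 of 23 rose and 0 fell (12 and 0 adjusted over the list alone); adjusted p = 0.0509), but was called higher after quantile normalization (adjusted p = 0.021) and equal medians (adjusted p = 0.011), without a filter (0.030), without trend (0.047) and with the repeat number as a block (0.041). It was also called higher without WT ES repeat 2 (0.045), WT ntTS repeat 1 (0.033), either WT TS repeat (0.022 and 0.023) or either WT XEN repeat (0.041 for both). Early germ layers were called lower (5 of 13 rose and 6 fell (5 and 6 adjusted over the list alone); adjusted p = 0.0424, and adjusted p = 0.468 with an estimated correlation) with a mean of -1.19 but a relative median of 0.021, and this call held in 14 of 25 settings. It was lost after quantile normalization (adjusted p = 0.20) or equal medians (0.19), with an added value of 1.91 (0.051), without a filter (0.17), with the mean of probe sets (0.059), every probe set (0.061) or only the compared groups (0.12). It was also lost without either TKO ES repeat (adjusted p = 0.053 and 0.052) or either WT ES+GATA4 repeat (0.059 for both).

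The trophectoderm and epiblast references, WT TS and WT ES cells, lay on 1 side of the spike-in split. Pluripotency genes were lower in TS cells. The Trophoblast stem and Epithelial lists were higher and the Germline list lower, and these 3 calls were lost with an estimated correlation (adjusted p = 0.0763, 0.396 and 0.0644). The test called 4286 genes higher and 3387 lower, 4166 at least 2-fold, around a median of 0.12. The split was 3749 and 4416 after quantile normalization and 3055 and 4503 after equal medians.

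Elf5 (8.40 ± 0.20, adjusted p = 1.70e-16), the glycogen phosphorylase gene Pygl (7.36 ± 0.25) and Gata3 (6.60 ± 0.28) rose. Tdgf1 (-9.41 ± 0.21, adjusted p = 1.02e-16) and Gsta4 (-8.91 ± 0.17) fell. Of Pluripotency 0 of 25 rose and 23 fell (0 and 23 adjusted over the list alone), with a median of -3.59 relative to all genes (adjusted p = 7.52e-16). Of Trophoblast stem 18 of 22 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 3.03 relative to all genes (adjusted p = 7.61e-10, and adjusted p = 0.0763 with an estimated correlation). Meg3 fell (-3.98 ± 0.18) in a maternally expressed list that was not called (adjusted p = 0.98). In Parietal endoderm 10 of 15 rose and 3 fell (10 and 3 adjusted over the list alone), with a median of 1.49 relative to all genes (adjusted p = 0.00417, and adjusted p = 0.401 with an estimated correlation). Of Germline genes 3 of 38 rose and 29 fell (3 and 29 adjusted over the list alone), with a median of -2.08 relative to all genes (adjusted p = 5.67e-09, and adjusted p = 0.0644 with an estimated correlation). In Epithelial junctions and keratins 14 of 21 rose and 3 fell (14 and 3 adjusted over the list alone), with a median of 1.56 relative to all genes (adjusted p = 2.06e-04, and adjusted p = 0.396 with an estimated correlation). Of Immediate early and heat shock 13 of 19 rose and 3 fell (14 and 3 adjusted over the list alone), with a median of 1.07 relative to all genes (adjusted p = 0.00231, and adjusted p = 0.401 with an estimated correlation). Of Feeder fibroblast 2 of 22 rose and 9 fell (2 and 9 adjusted over the list alone), with a median of -0.76 relative to all genes (adjusted p = 0.0047, and adjusted p = 0.0763 with an estimated correlation). Methylation machinery was called lower (4 of 17 rose and 9 fell (4 and 9 adjusted over the list alone); adjusted p = 0.0201, and adjusted p = 0.474 with an estimated correlation), but not after quantile normalization (adjusted p = 0.066). Early germ layers were called lower (4 of 13 rose and 7 fell (4 and 7 adjusted over the list alone); adjusted p = 0.0224, and adjusted p = 0.401 with an estimated correlation), but not after quantile normalization (adjusted p = 0.078) or equal medians (adjusted p = 0.064), nor without a filter (adjusted p = 0.075).

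WT XEN cells were compared with WT ES cells as the primitive endoderm against the epiblast reference. The Primitive, Parietal and Visceral endoderm lists were higher, and these 3 calls were lost with an estimated correlation (adjusted p = 0.0951, 0.0517 and 0.102). Pluripotency and germline genes were lower. The test called 5078 genes higher and 3559 lower, 5130 at least 2-fold, around a median of 0.22. The split was 4002 and 4914 after quantile normalization and 3633 and 4731 after equal medians.

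Pdgfra (7.97 ± 0.32, adjusted p = 1.87e-13), Gata6 (7.47 ± 0.24) and the peptidase gene Enpep (9.74 ± 0.30) rose, while Sox2 (-9.13 ± 0.17, adjusted p = 1.24e-17) and Nanog (-8.54 ± 0.23) fell. Of Primitive endoderm regulators and receptors 12 of 14 rose and 2 fell (12 and 2 adjusted over the list alone), with a median of 6.01 relative to all genes (adjusted p = 1.24e-05, and adjusted p = 0.0951 with an estimated correlation). Of Parietal endoderm 15 of 15 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 5.15 relative to all genes (adjusted p = 1.12e-11, and adjusted p = 0.0517 with an estimated correlation). Ttr, the thyroxine carrier, rose (8.24 ± 0.31), and in Visceral endoderm 15 of 16 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 3.52 relative to all genes (adjusted p = 1.05e-04, and adjusted p = 0.102 with an estimated correlation). In Pluripotency 3 of 25 rose and 21 fell (3 and 21 adjusted over the list alone), with a median of -5.03 relative to all genes (adjusted p = 7.92e-14). Of Germline genes 3 of 38 rose and 31 fell (3 and 31 adjusted over the list alone), with a median of -2.97 relative to all genes (adjusted p = 6.82e-10). In Methylation machinery 4 of 17 rose and 12 fell (4 and 12 adjusted over the list alone), with a median of -1.28 relative to all genes (adjusted p = 8.64e-04, and adjusted p = 0.313 with an estimated correlation). Of Early germ layers 2 of 13 rose and 9 fell (2 and 10 adjusted over the list alone), with a median of -1.80 relative to all genes (adjusted p = 9.51e-04, and adjusted p = 0.223 with an estimated correlation). In Feeder fibroblast 0 of 22 rose and 14 fell (0 and 14 adjusted over the list alone), with a median of -1.78 relative to all genes (adjusted p = 1.03e-04). Proliferation (1 of 24 rose and 11 fell (1 and 10 adjusted over the list alone); adjusted p = 0.026, and adjusted p = 0.639 with an estimated correlation) and p53 targets (5 of 21 rose and 11 fell (5 and 12 adjusted over the list alone); adjusted p = 0.0323, and adjusted p = 0.639 with an estimated correlation) were called lower, and neither was called without WT XEN repeat 2 (adjusted p = 0.054 for both). The maternally expressed list was called lower (4 of 25 rose and 10 fell (4 and 10 adjusted over the list alone); adjusted p = 0.0432, and adjusted p = 0.438 with an estimated correlation), but not after quantile normalization (adjusted p = 0.22) or equal medians (adjusted p = 0.090), without a filter (0.062) or with only the compared groups (0.10), nor without WT ES repeat 2 (0.051), WT ES+GATA4 repeat 1 (0.068) or repeat 2 (0.061), or TKO ntTS repeat 2 (0.055).

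ES cells with activated GATA4, a regulator of primitive endoderm, were compared with WT ES cells to see how far GATA4 brings the endoderm program. The endoderm regulators and basement membrane genes were higher. Pluripotency and germline genes were lower, and Pou5f1 fell less than in XEN cells. The test called 4183 genes higher and 2963 lower, 3654 at least 2-fold, around a median of 0.14. The split was 3532 and 4248 after quantile normalization and 2584 and 4686 after equal medians. The line carried a GATA4 transgene and was grown in other medium, and neither these nor the spike-in difference could be told apart from GATA4 activation.

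Pdgfra (8.03 ± 0.32, adjusted p = 6.62e-13), Gata6 (7.21 ± 0.24) and the retinoic acid hydroxylase gene Cyp26a1 (7.13 ± 0.37) rose. Of Primitive endoderm regulators and receptors 13 of 14 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 5.78 relative to all genes (adjusted p = 3.49e-11). Of Parietal endoderm 15 of 15 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 3.94 relative to all genes (adjusted p = 3.82e-15). Visceral endoderm was not called (7 of 16 rose and 1 fell (7 and 1 adjusted over the list alone); adjusted p = 0.07) except after equal medians (adjusted p = 0.018), with the filter at 87.3 (0.039), every probe set (0.014) or only the compared groups (0.017), without WT ES repeat 1 (0.047) or without WT ES+GATA4 repeat 1 (0.031). Nanog (-3.17 ± 0.23, adjusted p = 1.53e-09) and Pou5f1 (-1.48 ± 0.22) fell, and in Pluripotency 3 of 25 rose and 19 fell (3 and 19 adjusted over the list alone), with a median of -2.25 relative to all genes (adjusted p = 2.01e-09). Of Germline genes 3 of 38 rose and 25 fell (3 and 26 adjusted over the list alone), with a median of -2.11 relative to all genes (adjusted p = 3.80e-10). In Methylation machinery 3 of 17 rose and 11 fell (3 and 11 adjusted over the list alone), with a median of -0.86 relative to all genes (adjusted p = 0.00251, and adjusted p = 0.488 with an estimated correlation), and in Feeder fibroblast 2 of 22 rose and 13 fell (2 and 13 adjusted over the list alone), with a median of -1.17 relative to all genes (adjusted p = 0.00251).

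The 2 endoderm references were set against each other as WT XEN against WT ES+GATA4 cells. Gata4, Sox17 and Pdgfra did not pass. The Visceral endoderm list was higher in XEN cells, a call that was lost with an estimated correlation (adjusted p = 0.183). Pluripotency transcripts that remained in the GATA4 cells were lower in XEN cells. The test called 3020 genes higher and 2476 lower, but at least 2-fold 1174 were higher and 1210 lower. The split was 2822 and 3452 after quantile normalization and 3067 and 2310 after equal medians. Spike-in signal, dexamethasone and group could not be told apart.

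Afp, a serum carrier protein, rose (6.58 ± 0.34, adjusted p = 2.84e-11), as did Ttr (5.14 ± 0.31). Of Visceral endoderm 10 of 16 rose and 2 fell (10 and 2 adjusted over the list alone), with a median of 2.74 relative to all genes (adjusted p = 1.86e-04, and adjusted p = 0.183 with an estimated correlation). Of Parietal endoderm 8 of 15 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.43 relative to all genes (adjusted p = 0.00964, and adjusted p = 0.469 with an estimated correlation). Gata4 differed by 0.28 ± 0.24, adjusted p = 0.358, and Primitive endoderm regulators and receptors were not called (adjusted p = 0.22). Pou5f1 (-7.28 ± 0.22, adjusted p = 1.58e-14) and Dppa5a (-8.67 ± 0.16) fell, and of Pluripotency 2 of 25 rose and 21 fell (2 and 21 adjusted over the list alone), with a median of -2.49 relative to all genes (adjusted p = 1.69e-15). In Germline genes 2 of 38 rose and 15 fell (2 and 17 adjusted over the list alone), with a median of -0.61 relative to all genes (adjusted p = 0.00276, and adjusted p = 0.281 with an estimated correlation). Of Epithelial junctions and keratins 4 of 21 rose and 11 fell (5 and 11 adjusted over the list alone), with a median of -1.35 relative to all genes (adjusted p = 0.00221, and adjusted p = 0.469 with an estimated correlation). Of Early germ layers 0 of 13 rose and 6 fell (0 and 6 adjusted over the list alone), with a median of -0.99 relative to all genes (adjusted p = 0.00139, and adjusted p = 0.281 with an estimated correlation). Feeder fibroblast was called lower (2 of 22 rose and 8 fell (2 and 8 adjusted over the list alone); adjusted p = 0.00903, and adjusted p = 0.183 with an estimated correlation), but not after quantile normalization (adjusted p = 0.066). Immediate early and heat shock genes were called lower (3 of 19 rose and 10 fell (4 and 10 adjusted over the list alone); adjusted p = 0.0428, and adjusted p = 0.567 with an estimated correlation), but not after quantile normalization (adjusted p = 0.066), with the mean of probe sets (0.0504), without trend (0.070), without WT ES+GATA4 repeat 1 (0.11) or without WT XEN repeat 2 (0.059). The maternally expressed list was called lower (2 of 25 rose and 6 fell (2 and 6 adjusted over the list alone); adjusted p = 0.044, and adjusted p = 0.469 with an estimated correlation), but not after quantile normalization (adjusted p = 0.14), without a filter (0.091), with the filter at 87.3 (0.067) or without trend (0.059), nor without either TKO ES repeat (0.054 for both), WT ES+GATA4 repeat 2 (0.10), WT ntTS repeat 1 (0.052) or either TKO ntTS repeat (0.058 and 0.051).

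Whole profiles placed the ntTS lines beside TS cells. The mean correlation across genes of TKO ntTS arrays was 0.925 with WT ntTS, 0.914 with WT TS, 0.834 with WT ES+GATA4, 0.819 with TKO ES and 0.785 with WT XEN arrays. It was 0.936 between WT ntTS and WT TS arrays and 0.972 between TKO ES and WT ES arrays. Sets of genes higher in 1 reference than in the others held 455 ES, 298 TS and 490 XEN genes. In TKO ntTS against WT ntTS cells none of the sets was called in the main setting, with relative medians of 0.11 for the ES set (adjusted p = 0.70), 0.060 for the TS set (adjusted p = 0.75) and -0.014 for the XEN set (adjusted p = 0.75). In TKO ES against WT ES cells the XEN set was higher (0.21, adjusted p = 8.36e-08, and adjusted p = 0.41 with an estimated correlation). The ES set was lower there (-0.14, adjusted p = 0.030, and adjusted p = 0.41 with an estimated correlation) but not called without TKO ES repeat 2 or with the filter at 87.3 (-0.11 for both). The TS set was not called there (0.059, adjusted p = 0.15) except without WT ES repeat 1 (0.079) or with sets made at 8-fold (0.18). The TS set was lower in WT ntTS (-0.67, adjusted p = 1.73e-20) and in TKO ntTS cells (-0.57, adjusted p = 3.27e-13) than in WT TS cells, from which it was made. In WT ntTS against WT TS cells the ES set (0.33, adjusted p = 5.30e-06, and adjusted p = 0.076 with an estimated correlation) and the XEN set (0.31, adjusted p = 1.36e-05, and adjusted p = 0.24 with an estimated correlation) were higher. In TKO ntTS against WT TS cells the ES set (0.65, adjusted p = 1.89e-07) and the XEN set (0.38, adjusted p = 2.66e-04, and adjusted p = 0.31 with an estimated correlation) were higher as well. Comparisons with WT ES or WT TS cells are not independent of the sets, and the latter held the fibroblast difference.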

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

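The scaling check in this part was chosen after the result was seen. Genotype effects that differed between ntTS and ES cells come first, then unused control transcript signals.

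The test of the difference called 2474 genes. By list, relative to all genes, the effect in ntTS cells was higher by a median of 3.65 for Differentiated trophoblast and 1.46 for Germline genes. It was lower for Primitive endoderm regulators and receptors (-1.45) and Parietal endoderm (-0.55). With an estimated correlation, only the Differentiated trophoblast call was kept, and the others had adjusted p-values of 0.336, 0.119 and 0.308. The genes with the highest differences were Prl4a1 (8.34), Pla2g5 (7.52), Ceacam15 (7.48), Prl8a9 (7.11) and Rhox13 (6.99), and those with the lowest were Gna13 (-5.16), Vnn1 (-4.88), Igf2 (-4.85), Pdgfb (-4.83) and Slc16a6 (-4.70).

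The mean signals of the control transcripts on the 6 arrays of WT ES+GATA4, WT ntTS and TKO ntTS cells, as ratios to the other 8 arrays, were 15.7 for dap, 9.18 for lys, 10.8 for phe and 17.99 for thr.

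Genes of differentiated trophoblast were higher in TKO ntTS than in WT ntTS cells. Cross-hybridisation between family members stays open. The list's 20 probe sets named for unique probes (median 4.59 relative to all probe sets, 16 called higher) were not limited to families. Array scaling is argued against by the list's call after quantile normalization, with an adjusted p of 6.23e-10. A small share of differentiated trophoblast cells in the TKO ntTS cultures stays open, since 5 of 9 members outside the prolactin, cathepsin and Psg families were called higher, next to 13 of 14 within them. Of those 9, Phlda2 (-5.50) and Gjb2 (-1.60) were called lower, which added cells alone would not bring about. Transcription of these genes in the TKO stem cells themselves, and a difference between the lines, may contribute as well and were not tested.

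Of 8 neighbouring genes in the GRCm38.p6 assembly, from Gna13 to Map2k6, 7 were called at least 2-fold lower in TKO ntTS than in WT ntTS cells, a group chosen after its values were seen. Chance order of genes is argued against by shuffling: 0 of 10000 shuffled orders held such a window, and the largest held 6. Absence of the 3 DNA methyltransferases in any cell as a sufficient cause is argued against by ES cells, where the median difference of these genes relative to all genes was 0.12. Loss of the DNA segment in the TKO ntTS line cannot be told apart from lower transcription, because 4 of the 8 genes lay under the filter level in TKO ntTS cells, with Arsg among them, which was not called lower (-0.50), and 1, Prkar1a, lay above 4 times that level. The TKO ntTS group held 1 line, so that a property of that line may be the source of the 7 falls.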

How the results depend on the processing

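Under the alternatives 776 values held, 103 moved, 4 gained a call, 2 lost one and 7 reversed. Counts and correlations were held to a set margin, lineage sets to direction and call. Every list call in the TKO against WT comparisons, their difference and WT ntTS against WT TS held in the 25 settings that kept the preset correlation. The cause of the changes below was not tested unless stated. The fits restricted to arrays with alike spike-in signals were chosen after seeing the data and called 3232 genes higher and 1241 lower in TKO ntTS against WT ntTS, and 449 and 357 in TKO ES against WT ES. Array signal limits the dim genes, whose differences the added value of 7.65 pulls towards 0.

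With every probe set tested, more units were counted: 6984 calls in TKO ntTS against WT ntTS, 3730 in the difference between the genotype effects, 7191 in WT ntTS against WT TS, 11033 in TKO ntTS against WT TS, 14184 in TKO ntTS against TKO ES, 13386 in WT ntTS against WT ES, 13814 in WT TS against WT ES, 15351 in WT XEN against WT ES, 12358 in WT ES+GATA4 against WT ES and 9418 in WT XEN against WT ES+GATA4. Lists called were then 7 in TKO ntTS against WT ntTS, 7 in the difference, 2 in WT ntTS against WT TS and 12 in WT ES+GATA4 against WT ES. With the 2-fold threshold, which drops small differences by construction, the counts in the report's order of comparisons were 1667, 438, 1586, 1485, 2466, 4392, 4078, 4166, 5130, 3654 and 2384. That threshold gives no value for the list and set tests, the correlation and the similarity.

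With only the compared groups in the fit, 1658 genes were called in TKO ES against WT ES and 3779 in the difference. Quantile normalization gave 1616 in TKO ES against WT ES. With an estimated correlation, lists called were 4 in TKO ES against WT ES, 1 in the difference, 3 in TKO ntTS against WT TS, 2 in TKO ntTS against TKO ES, 3 in WT ntTS against WT ES, 1 in WT TS against WT ES, 3 in WT XEN against WT ES and 1 in WT XEN against WT ES+GATA4. With fry they were 7 in WT ntTS against WT TS, 11 in TKO ntTS against WT TS, 14 in WT ntTS against WT ES, 12 in WT ES+GATA4 against WT ES and 14 in WT XEN against WT ES+GATA4. Without a filter, and with the mean of probe sets, 2 lists were called in WT ntTS against WT TS.

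In TKO ntTS against WT ntTS, the ES set reversed to -0.0013 with an added value of 30.6 and was called at 0.13 with equal medians. The TS set was called at 0.060 with only the compared groups and reversed to -0.025 with sets made at 2-fold. The XEN set reversed to 0.022 with an added value of 1.91, 0.0061 with every probe set and 0.076 with sets at 2-fold. In TKO ES against WT ES, the ES set lost its call with the stricter filter (-0.11) and the TS set was called with sets at 8-fold (0.18). After quantile normalization, Proliferation was also called lower in the difference (adjusted p = 0.030), in WT ES+GATA4 against WT ES (0.044) and in WT XEN against WT ES+GATA4 (0.031). After equal medians it was called lower in WT ES+GATA4 against WT ES (0.016). Interferon response was then higher in WT ntTS (0.028) and WT TS (0.045), and Differentiated trophoblast in WT TS (0.045), against WT ES.

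Genes higher in both genotype comparisons were 125 with equal medians, 387 with only the compared groups and 80 with the 2-fold threshold. Genes lower in both were 277 with quantile normalization, 197 with only the compared groups and 34 with the 2-fold threshold. The correlation of the differences was 0.12 without a filter and 0.18 with the stricter filter. The similarity of TKO ntTS to WT ntTS, WT TS and TKO ES arrays was 0.917, 0.903 and 0.802 with an added value of 1.91, 0.936, 0.926 and 0.840 with an added value of 30.6, 0.952, 0.943 and 0.895 without a filter, and 0.909, 0.894 and 0.769 with the stricter filter. It was 0.924, 0.911 and 0.817 with the mean of probe sets, 0.930, 0.907 and 0.836 with every probe set, and 0.927 and 0.916 for WT ntTS and WT TS with quantile normalization.

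Leaving out 1 array at a time assumes that the remaining array of a group varies like the other groups. Counts ranged from 2641 to 4689 in TKO ntTS against WT ntTS, 407 to 1307 in TKO ES against WT ES, 1613 to 2922 in the difference, 2173 to 4259 in WT ntTS against WT TS and 3958 to 6373 in TKO ntTS against WT TS. Lists called in WT ntTS against WT TS ranged from 1 to 4. The XEN set ranged from -0.041 to 0.034 in TKO ntTS against WT ntTS, the ES set from -0.15 to -0.11 and the TS set from 0.051 to 0.079 in TKO ES against WT ES. Genes higher in both comparisons ranged from 76 to 300 and lower in both from 52 to 136, and the correlation from 0.14 to 0.16. Similarities ranged from 0.925 to 0.927 for WT ntTS, 0.913 to 0.915 for WT TS and 0.818 to 0.823 for TKO ES.

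Of the values of single genes under the alternatives, 3449 kept direction and call, 11 lost and 6 gained a call, and 9 reversed, all 9 for genes not called. Cdx2 in TKO ntTS against WT ntTS reversed to -0.12 with quantile normalization, -0.20 with equal medians and -0.021 with the mean of probe sets. With 1 array left out, Pou5f1 in TKO ES against WT ES ranged from -0.099 to 0.045. In WT XEN against WT ES+GATA4, Gata4 ranged from -0.019 to 0.59, Pdgfra from -0.16 to 0.040 and Sox17 from -0.32 to 0.19.

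The groups share repeat numbers, but these did not pair the arrays: over 21 pairs of groups, the correlation of the differences between repeat 1 and repeat 2 was -0.077 to 0.053. With the repeat number as a block, 4021 genes were called in TKO ntTS against WT ntTS and 880 in TKO ES against WT ES. The block moved no count of genes by more than 1.5 times, and among list calls it added Differentiated trophoblast in WT ntTS against WT ES (adjusted p = 0.041).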

Other observations

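The tests of array scaling and of lower expression in cells without the 3 DNA methyltransferases were chosen after the result was seen, and the runs of neighbours described next were found in the data. Genes that rose in TKO ntTS cells lay together in the GRCm38.p6 gene order. There were 10 runs of at least 4 adjacent tested genes each called at least 2-fold higher, and 1000 shuffled orders held 4 at most, with a median of 1. The longest held 10 genes, 9 of them of the prolactin family from Prl8a9 to Prl5a1, with differences of 1.30 to 9.81. A run of 9 held placental cathepsins, Tpbpa and the Ctla2 genes (1.91 to 6.67). A run of 7, from Zfp980 to Zfp979 with Rex2, held mostly zinc-finger genes (1.12 to 5.09), and a run of 6 held serine protease inhibitor genes from Serpinb6b to Serpinb9g (3.10 to 4.45). Shorter runs included the germline genes Tex19.1 and Tex19.2. The median differences of these 4 longest runs in TKO ES against WT ES cells were 0.39, 0.27, 0.13 and 0.27.

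Sex-linked transcripts differed between lines. Of the WT TS arrays, repeat 1 had Xist at 7862 and the Y-linked genes Eif2s3y at 1.16 and Uty at 0.458, and repeat 2 had 82.8, 574 and 158. WT XEN cells had Xist at 8828 ± 1.51 and Eif2s3y at 3.12 ± 3.15, and the other groups had Eif2s3y at 765 ± 30.9 (WT ntTS) to 1271 ± 249 (TKO ES). The comparisons with WT TS or WT XEN cells therefore included a difference in sex chromosomes.

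The Feeder fibroblast list was lower in TKO ntTS than in WT ntTS cells, with 12 of 22 members called lower. Different amounts of feeder cells would keep 1 ratio. Over 21 members, the excess over WT TS cells in TKO ntTS cells was 9.30% (Tagln) to 123% (Dcn) of that in WT ntTS cells. The SD of the log2 fractions was 4.84 times the median SE between repeats. That SE omits differences between the lines' feeders, so feeder amounts as the whole cause stay undecided. The list's call after quantile normalization (camera, adjusted p = 3.01e-06) does not test array scaling, as a shared shift could hardly remove it. Calls of single members can change with scaling, and 0 of 22 were then higher and 14 lower. Lower expression in cells without the 3 DNA methyltransferases stays open, as the list was also lower in TKO ES cells, by a median of -0.48, so that the cells' own expression may add to a change in feeders.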
